A study of Mus musculus with 8 samples.

How the data were processed

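The data were gene counts of IELs from 8 mice, 4 given anti-CD3 with PBS and 4 given anti-CD3 with exendin-4. Per the labels' protocols, RNA was prepared with TRIzol from Percoll-enriched, CD45-sorted gut cells, and libraries were made with the strand-specific TruSeq mRNA kit. They were sequenced on a NovaSeq with paired reads of 200 bp, per the labels. STAR 2.7.9a, DESeq2 and the build mm10 are named, per the submitters' processing notes, without their role or order, and the read counter and the annotation are not given in the sources used here. The authors deposited whole-number counts per gene, not normalised, for 25230 gene symbols, of which 21452 had a count in at least 1 library. The 8 columns were each matched to a mouse by its description, and 0 per-sample columns were left unused. Of the symbols 25032 were found in the RefSeq annotation of GRCm38, which gave the coordinates, and 24366 in GENCODE. The table held 0 mitochondrially encoded genes.

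Groups and replicate numbers were taken from the labels, which describe separate mice but state no litter, cage, batch or day. Total counts were 19477917, 25333644, 19622004 and 18266449 for PBS 1 to 4 and 22009510, 26778167, 31843413 and 13386889 for Ex4 1 to 4, so that the shallowest library gives the least precise values of genes at a few CPM. Every pair of replicates differed by more than sampling noise, with a mean chi-square per gene from 22.1 to 82.7, so all 8 libraries were counted separately. The Y-linked gene Ddx3y had 2715 to 6820 counts in each library and Xist 0 to 42. Genes detected were also counted after each library was thinned to 13386889 counts, as a mean of 5 draws.

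Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM scaling, robust dispersions and the quasi-likelihood F test of exendin-4 against PBS, with Benjamini-Hochberg adjustment over 14691 genes and a threshold of 0.05. SEs of log2 fold changes were derived from the fitted value and its F statistic. The comparison, its test, 31 gene lists with 697 genes, the rule for naming genes and all but 3 alternatives were fixed before the data were examined. Named genes were those past the threshold with a mean log2 CPM of at least 1 and no overlap between groups, up to 10 per direction. Where fewer than 5 passed in a direction, it was filled to 5 by the smallest unadjusted p. The 4 members of each list with the smallest p were added, with Glp1r, Ifng, Tnf, Il2, Gzmb, Cd69, Nr4a1, Crem, Cd8a and Itgae. Predicted genes, Rik clones and antigen receptor segments were not named. Il22, Iltifb, Cars, Iars, Kars, Aars, Rbm3, Cd1d2 and the stromal genes of a later test fell outside this rule and were chosen after their values were seen, or for a later test. Some results were left out and are not reported here.

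Of the lists, 30 were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and also with an estimated correlation and with fry. The list of sex-linked genes served only as a check of the animals (median log2 fold change 0.05) and was not tested. List genes absent from the table numbered 16, among them the antigen receptor constant genes, so that the receptor type of the IELs was not measured here. Principal components were computed on log2 CPM with a prior count of 2. Differences on the components and in list scores were tested with exact two-sided permutation over 70 assignments, and correlations over all 40320 orders of the 8 libraries.

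Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters, each library left out in turn, a replicate block, the run of label numbers, an epithelial score and 1 surrogate variable (sva 3.50.0) as terms. A threshold of 0.1, a test against a 1.2-fold change and omission of the 10 most abundant genes were also run. Gzma alone took 4.41% of all counts and Gzmb 1.93%.

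The test was checked on simulated counts for this comparison, drawn from the means, dispersions and library sizes of the 14691 genes with 200 of them changed. In edgeR, which kept 14277 of the simulated genes, 11.9% of genes changed 1.5-fold, 34.3% of those changed 2-fold and 56.1% of those changed 3-fold were recovered, all in the right direction, and 7 of 75 calls were false. In DESeq2 the shares were 20.9%, 44.8% and 63.6%, and 24 of 110 calls were false. A simulated list of 25 genes lowered by 0.25 on the log2 scale gave a camera p of 7.92e-07, and 25 unchanged genes gave 0.943. Each simulated gene was drawn independently, whereas the lists called in the real data had estimated correlations from 0.063 to 0.662. The simulation therefore cannot check how often camera at the preset correlation calls lists whose members vary together. Matching of random lists on transcript length and GC content used GENCODE transcripts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for library tables and figures.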

Results

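Intraepithelial lymphocytes (IELs), the T cells that lie between the epithelial cells of the gut lining, were profiled by strand-specific mRNA sequencing in 8 C57BL/6J mice. All 8 animals received 35 µg of an antibody against CD3, which activates T cells through their receptor complex. PBS was given to 4 of them, and 4 received exendin-4 (Ex4), an agonist of the GLP-1 receptor, at 10 nmol/kg. Gut cells were taken after 3 hours, enriched on Percoll and sorted for CD45, a surface protein of leukocytes. Total gene counts were 19477917, 25333644, 19622004 and 18266449 in PBS replicates 1 to 4 and 22009510, 26778167, 31843413 and 13386889 in Ex4 replicates 1 to 4. Values after ± are SDs over 4 libraries in CPM, the gene counts scaled to a common library size, except where an SE is named.

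The comparison asked how exendin-4 altered the transcriptome of IELs activated through CD3. Flna, which encodes the actin cross-linking protein filamin A, rose from 43.6 ± 6.47 CPM with PBS to 130.4 ± 17.9 CPM with exendin-4. Its log2 fold change was 1.58 (SE 0.15), with an adjusted p of 0.000451 (edgeR quasi-likelihood test, Benjamini-Hochberg). Cd1d1, which encodes a surface molecule that presents lipids to natural killer T cells, rose from 40 ± 6.78 to 80.2 ± 6.81 CPM. Its log2 fold change was 1.00 (SE 0.14), with an adjusted p of 0.0386 in the same edgeR test. For both genes every Ex4 library lay above every PBS library. Flna lies on chromosome X from 74223461 to 74249854 and Cd1d1 on chromosome 3 from 86995834 to 87012358 in GRCm38, the assembly also called mm10, and each value covers the whole gene. Cd1d1 has a near-identical neighbour, Cd1d2, so its count is uncertain to the extent that reads were split between them. The increase of Cd1d1 lost its call when any library except PBS 2 was left out (adjusted p from 0.104 to 0.31 in the edgeR test). Its adjusted p ran from 1.19e-05 with DESeq2 to 0.313 over 24 alternatives, whereas Flna was called in each of them.

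Of 14691 genes tested, these 2 passed, and 0 were lower with exendin-4 in the edgeR test. At an unadjusted p under 0.05 there were 545 genes higher and 573 lower, 1118 in all against 735 expected by chance. The groups did not overlap for 727 genes, or 4.95% of those tested, where chance gives 2.86%. Both chance values are averages, and a single comparison can lie far from them when genes vary together. Neither count was made for other splits of the libraries, so an excess over chance was not tested. DESeq2 called 75 genes, 43 higher and 32 lower, and limma-voom called 1 higher and 0 lower. Without PBS replicate 2 edgeR called 14 genes, 10 higher and 4 lower, and without any other single library it called 1. With the log2 total counts of each library as a covariate it called Flna (1.57) and, as lower, Crtam, an adhesion receptor gene of cytotoxic cells (log2 fold change -1.09, edgeR adjusted p = 0.0317).

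**Figure D1:**
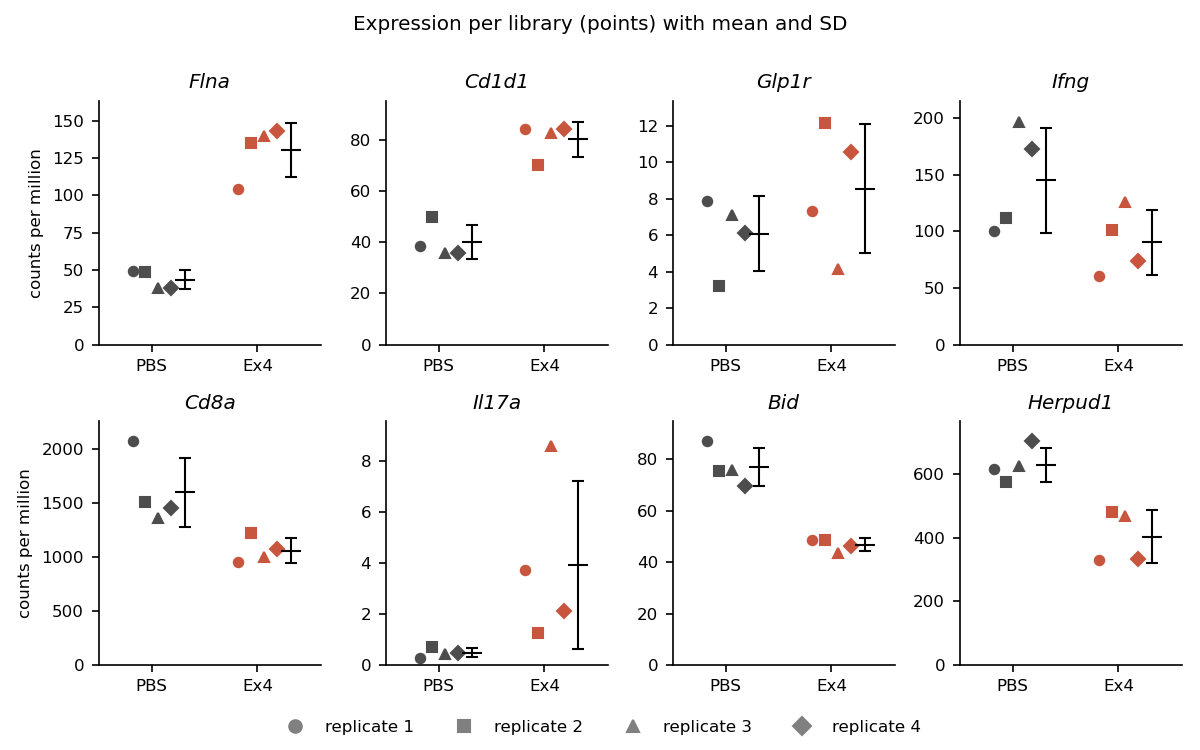
Expression in CPM (vertical axes, linear, from 0) of 8 genes in each PBS and Ex4 library, where marker shapes stand for replicates 1 to 4 and bars for the mean and SD. Flna and Cd1d1 passed the edgeR test, with means of 43.6 against 130.4 and 40 against 80.2 CPM, and the other 6 genes did not.

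The 8 further genes named for their small p-values did not pass the edgeR test, although DESeq2 called each of them (adjusted p from 0.00051 to 0.00724). Among those with a higher mean in Ex4, Fam107b was at 115.9 ± 19.2 and 212.2 ± 30.8 CPM in PBS and Ex4 (log2 fold change 0.87, edgeR adjusted p = 0.165). Cirbp, which encodes a cold-inducible RNA-binding protein, was at 107.0 ± 20.2 and 192.1 ± 30.7 CPM (0.84, edgeR adjusted p = 0.249). Pigx, a gene of glycosylphosphatidylinositol anchor synthesis, had a log2 fold change of 0.71. Among those with a lower mean, Bid, which encodes a pro-apoptotic BCL2 family member, was at 77.0 ± 7.44 and 46.8 ± 2.48 CPM (-0.72, edgeR adjusted p = 0.165). Pabpc4, a poly(A)-binding protein gene, had a log2 fold change of -0.66, and Septin11, a gene of the septin cytoskeleton, of -0.97. Tagap1 had a log2 fold change of -0.73, and Spp1, which encodes osteopontin, was at 36.3 ± 7.68 and 16.4 ± 5.43 CPM (-1.15). The adjusted p-values of these 8 genes ran from 0.165 to 0.253 in the edgeR test.

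Glp1r, which encodes the receptor that exendin-4 binds, was detected in all 8 libraries, at 6.08 ± 2.05 CPM with PBS and 8.55 ± 3.54 CPM with exendin-4. Its log2 fold change of 0.49 (SE 0.37) did not pass the test (edgeR adjusted p = 0.819), and it was 0.25 without Ex4 2, 0.26 without PBS 2 and 0.70 without Ex4 3. Among 21 components of the GLP-1 receptor pathway 0 passed over all genes tested and 1 was higher when adjusted over the list alone. That gene was Prkacb, a catalytic subunit of protein kinase A, at 99.1 ± 8.31 and 144.2 ± 26.7 CPM. In that list the median log2 fold change was -0.01, the mean 0.07 and the camera direction up (adjusted p = 0.826). The cAMP, PKA and CREB response list had a median of 0.17 over 23 tested members (camera adjusted p = 0.606, and 0.0281 with direction up without PBS 4), with 0 members called over all genes or when adjusted over the list alone. Of its members, Crem had a log2 fold change of 0.60 (SE 0.34), Nr4a1 of 0.58 (SE 0.27), Icam1 of -0.53 (SE 0.16) and Pde4a of -0.68 (SE 0.23), and none of them passed the edgeR test. Without PBS 1 the values of Crem, Nr4a1 and Pde4a were 0.32, 0.35 and -0.41, and without Ex4 1 that of Nr4a1 was 0.38.

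The lists of T cell activation gave no call with all 8 libraries. The early activation list had a median log2 fold change of -0.01, a mean of 0.06 and a camera direction of down (adjusted p = 0.903), and the T cell receptor signalling list a median of 0.11 (camera adjusted p = 0.37, and 0.0203 with direction up without PBS 2), with 0 members passing in either over all genes or when adjusted over the list alone. Cd69, an early activation marker, was at 1247 ± 104 and 1126 ± 358 CPM. Among 19 tested proinflammatory cytokines 0 passed over all genes, and 3 were higher and 2 lower when adjusted over the list alone. The list had a median of -0.20, a mean of 0.10 and a camera direction of down (adjusted p = 0.482). Il17a, a cytokine of type 17 lymphocytes, was at 0.473 ± 0.172 and 3.92 ± 3.28 CPM, Il22, which acts on epithelial cells, at 112 ± 62.0 and 279 ± 74.2 CPM, and Il1b at 17.3 ± 4.29 and 27.0 ± 6.51 CPM. Tnfsf14 (log2 fold change -0.74) and Tnfsf10 (-0.48) were the members lower by that adjustment. Ifng, the main macrophage-activating cytokine of these cells, was at 145.3 ± 46.4 and 90.3 ± 28.9 CPM (-0.69, edgeR adjusted p = 0.554). Tnf had a log2 fold change of -0.24 (SE 0.35) and Il2 of -0.02 (SE 0.59), and neither passed. With 1 library left out Tnf ran from -0.55 (without Ex4 2) to -0.085 (without Ex4 4), and Cd69 from -0.38 (without Ex4 3) to -0.027 (without Ex4 4).

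Camera with its preset correlation of 0.01 called 5 of 30 gene lists, 4 lower and 1 higher with exendin-4. The unfolded protein and amino acid response list was lower, with a median log2 fold change of -0.27 over 25 genes, 20 of them below 0 (adjusted p = 5.51e-06, and adjusted p = 0.369 with an estimated correlation). None of its members passed over all genes, and 2 were lower when adjusted over the list alone: Creld2, at 338 ± 21.6 and 214 ± 47.1 CPM, and Herpud1, at 631 ± 53.4 and 404 ± 83.5 CPM, both genes of endoplasmic reticulum protein quality control. The ribosome biogenesis and MYC target list was lower, with a median of -0.20 and 27 of 27 genes below 0 (adjusted p = 4.41e-07, and adjusted p = 0.845 with an estimated correlation). Wdr12 (-0.48), Ppan (-0.33), Srm (-0.32) and Rrp9 (-0.29) had its smallest p-values. The cholesterol synthesis list was lower, with a median of -0.30 and 21 of 22 genes below 0 (adjusted p = 5.51e-06, and adjusted p = 0.845 with an estimated correlation). In these last 2 lists 0 members passed over all genes or when adjusted over the list alone. None of the 5 calls held with an estimated correlation, and 29 of the 35 splits of the libraries into 4 and 4 called at least 5 lists.

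**Figure D2:**
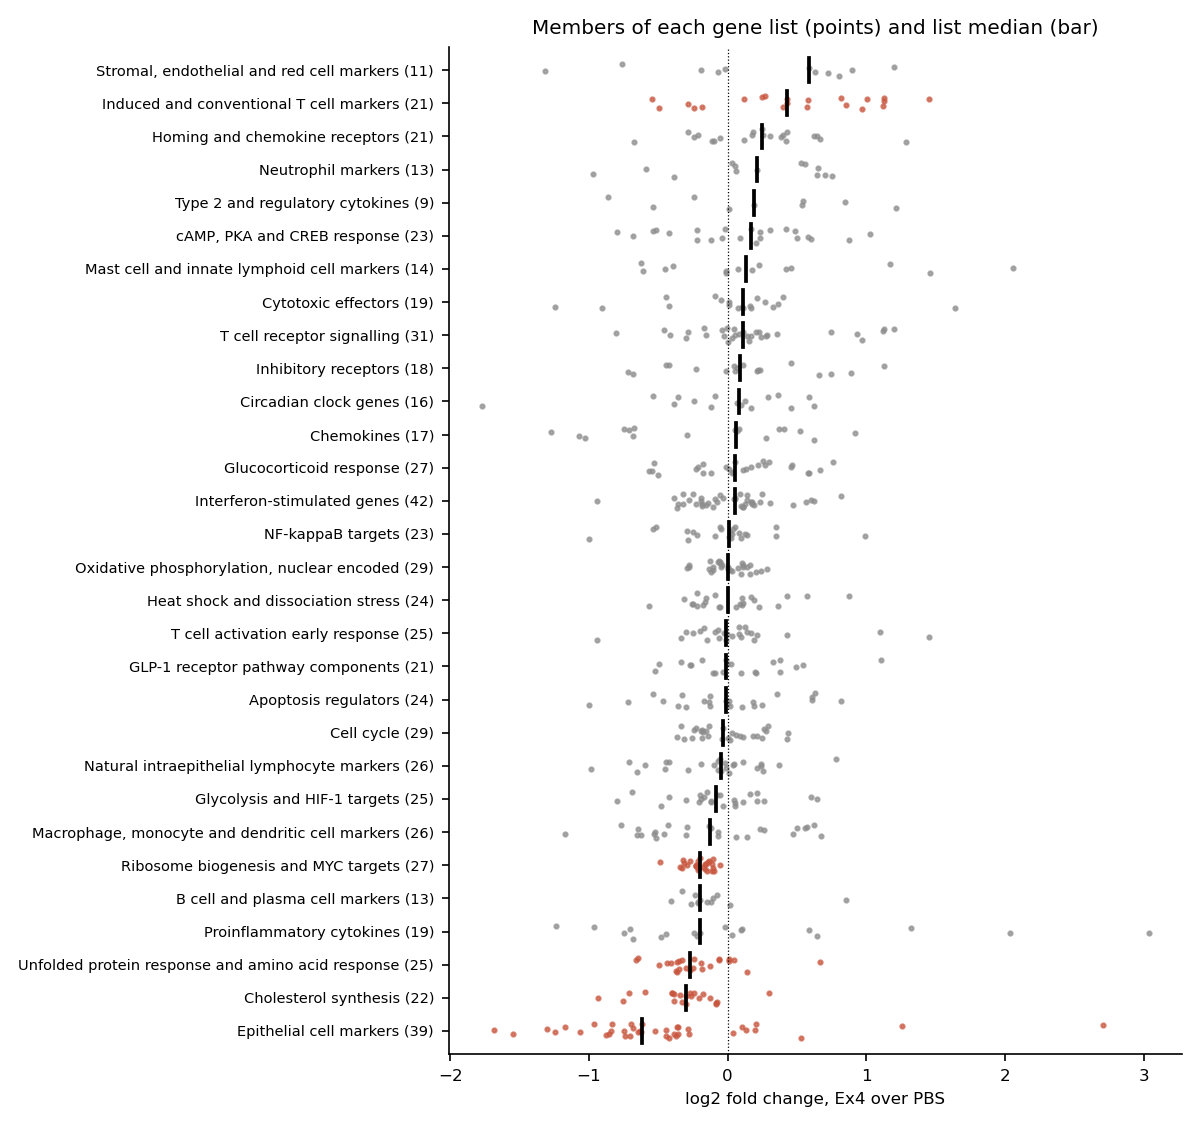
Log2 fold change of Ex4 over PBS (horizontal axis) of each tested member of the 30 gene lists, with the number of tested members in brackets and a bar at the list median; red lists were called by camera with the preset correlation. The ribosome biogenesis list lies wholly below 0, with a median of -0.20.

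Fry, which tests whether the genes of a set move on balance one way and compares them with no other genes, gave an adjusted p of 0.179 for the unfolded protein list and 0.404 for the ribosome biogenesis list. Its mixed form, which tests for changes in either direction, gave adjusted p = 0.0326 for the unfolded protein list and at least 0.0656 for every other list. The mean log2 CPM of the unfolded protein list was 6.40 ± 0.06 with PBS and 6.18 ± 0.04 with exendin-4, and that of the ribosome biogenesis list 7.39 ± 0.04 and 7.17 ± 0.14. In both lists the groups did not overlap, with an exact two-sided permutation p of 0.0286, the smallest that 70 assignments allow. The homing receptor list also reached 0.0286 in this exact test, among 30 lists tested. The scores of the other 3 lists that camera called overlapped between the groups, with an exact permutation p of 0.257 for cholesterol synthesis, 0.0571 for the conventional T cell list and 0.429 for the epithelial list. Cholesterol synthesis scores ran from 5.65 to 6.40 with PBS and from 5.29 to 5.98 with exendin-4, and PBS 1 held the 6.40, against at most 5.94 in the other PBS libraries.

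**Figure D3:**
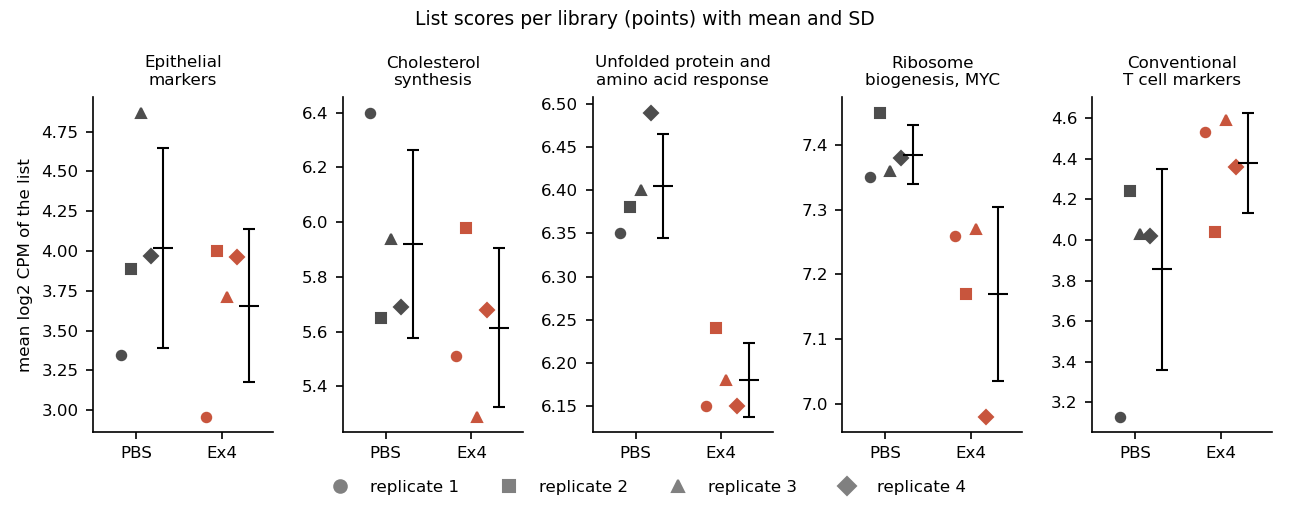
Mean log2 CPM (vertical axes, not from 0) of the 5 lists that camera called, in each PBS and Ex4 library, where marker shapes stand for replicates 1 to 4 and bars for the mean and SD. The unfolded protein scores were 6.40 ± 0.06 and 6.18 ± 0.04, without overlap, whereas the epithelial scores overlapped.

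Markers of other lymphocytes and of other cells in the gut wall gave mixed values. The list of induced and conventional T cell markers was higher, with a median log2 fold change of 0.43 over 21 genes (camera adjusted p = 0.00472, and adjusted p = 0.845 with an estimated correlation), and its call was lost without Ex4 3 (adjusted p = 0.0999) and with members shared with other lists removed (adjusted p = 0.284). Among its members, the costimulatory receptor gene Icos was at 55.7 ± 38.4 and 152.3 ± 50 CPM, and Themis, Cd2 and Il7r had log2 fold changes of 1.13, 0.81 and 0.58 (Il7r 0.37 without Ex4 3), with 0 members passing over all genes or when adjusted over the list alone. PBS 1 had the lowest score of this list, 3.13 against 4.02 to 4.24 in the other PBS libraries. The log2 fold change of Icos was 1.45 and fell to 1.11 without PBS 1, where Themis had 0.816 and Cd2 0.589. The natural IEL marker list had a median of -0.05 (camera adjusted p = 0.361), and by adjustment over the list alone 1 gene was higher, Klra7 (0.78), and 1 lower, Cd8a, at 1600 ± 322 and 1060 ± 116 CPM. Itgae, the integrin that holds IELs to the epithelium, was at 332 ± 92.5 and 311 ± 56.9 CPM. The epithelial marker list was lower, with a median of -0.62 over 39 genes (camera adjusted p = 5.51e-06, and adjusted p = 0.845 with an estimated correlation), and 0 members passed over all genes or over the list alone. Epcam was at 161 ± 16.4 and 125.6 ± 19.9 CPM. The epithelial score was highest in PBS 3 at 4.87, and without that library the list was not called (0.113).

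Among 19 tested cytotoxic effectors 0 passed over all genes, and 2 were higher and 2 lower when adjusted over the list alone (median 0.11, camera adjusted p = 0.826). Gzmk and Klrd1 had log2 fold changes of 1.64 and 0.36, and Gzmc and Crtam of -1.24 and -0.90. Gzmb, a granule protease that kills target cells, was at 19240 ± 3990 and 19410 ± 1830 CPM. Of the apoptosis regulators (median -0.01, camera adjusted p = 0.453) 1 gene, Bid, was lower when adjusted over the list alone, and Bcl2l1, which encodes the survival protein BCL-XL, was at 317.9 ± 149 and 158.8 ± 48.9 CPM (log2 fold change -1.0, and -0.63 without PBS 1). In the heat shock and dissociation stress list (median 0, mean 0.03, camera direction up, adjusted p = 0.826) 1 gene was higher by that adjustment, Zfp36, which encodes an mRNA-destabilising protein, at 84.0 ± 10.9 and 125.0 ± 14.1 CPM. In the mast cell and innate lymphoid list (median 0.13, camera adjusted p = 0.368, and 0.0125 without PBS 1) 1 was higher, the transcription factor gene Rora, at 13.9 ± 5.35 and 38.2 ± 15.3 CPM. In the stromal, endothelial and red cell list (median 0.59, adjusted p = 0.826) 1 was lower, Pecam1 (-0.76). Which of the sorted cells its counts came from was not tested. None of these members passed the edgeR test over all genes.

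In the other 14 lists 0 members passed over all genes or when adjusted over the list alone. Their medians and camera adjusted p-values were 0.19 and 0.826 for type 2 and regulatory cytokines, 0.25 and 0.361 for homing and chemokine receptors, 0.09 and 0.44 for inhibitory receptors, and 0.05 and 0.361 for the glucocorticoid response. Interferon-stimulated genes had 0.05 and 0.826, glycolysis and HIF-1 targets -0.08 and 0.44, nuclear-encoded oxidative phosphorylation 0 and 0.826, and cell cycle genes -0.03 and 0.826. B and plasma cell markers had -0.20 and 0.483 (0.00453 without Ex4 3), macrophage, monocyte and dendritic cell markers -0.13 and 0.826, and neutrophil markers 0.21 and 0.482. Chemokines had a median of 0.06, a mean of -0.19 and a camera direction of down (0.453, and 0.0113 without both PBS 2 and Ex4 3). NF-kappaB targets had a median of 0.01, a mean of -0.04 and a direction of down (0.606, and 0.0455 without PBS 1), and circadian clock genes a median of 0.08, a mean of -0.05 and a direction of up (0.826). The members with the smallest p in their own list included the chemokine gene Ccl1, at 7.77 ± 4.89 and 3.21 ± 0.562 CPM, the gut-homing receptor gene Ccr9, at 59.4 ± 19.6 and 37.1 ± 3.73 CPM, and the growth factor gene Tgfb3, at 148.6 ± 55.8 and 81.7 ± 22.1 CPM. Without PBS 1 the log2 fold change of Ccl1 moved from -1.27 to -0.75, that of Ccr9 from -0.68 to -0.43 and that of Tgfb3 from -0.863 to -0.585.

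No difference between the groups was detected along the first principal component of log2 CPM, which held 32.8% of the variance (exact permutation p = 0.543, two-sided). The second, with 17.4%, gave an exact p of 0.0571, and the third, with 13.2%, an exact p of 0.571, where the smallest possible was 0.0286. The first component followed the number of genes detected at matched depth over the 8 libraries (Pearson r = -0.97, exact permutation p = 9.9e-05, adjusted 2e-04 over 2 relations, and Spearman rho = -0.93, exact p = 0.0022). Without the 2 libraries farthest from the median r was -0.92. Its relation with total counts (r = 0.81, exact permutation p = 0.016, adjusted 0.016, and rho = 0.57, exact p = 0.15) rested on the 2 farthest libraries, without which r was 0.48. PBS 2 and Ex4 3 had the fewest genes at matched depth, 16123 and 16485, against 17534 to 19087 in the others, and without both of them 2 genes were called.

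**Figure D4:**
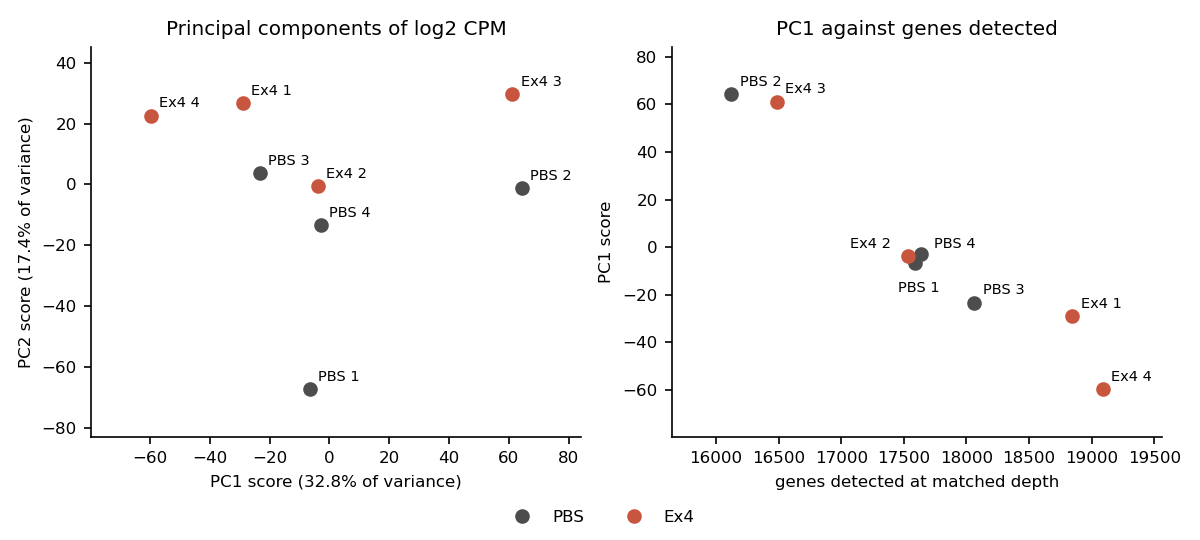
Left, scores of the PBS and Ex4 libraries on the first and second principal components of log2 CPM; right, the first component against the number of genes detected after thinning to the smallest total. PBS 2 and Ex4 3 sit together at the high end of the first component with 16123 and 16485 genes, and PBS 1 sits apart at -67.5 on the second.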

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

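All comparisons in this part followed a rule set in advance. In each group of 4 libraries, the gap between the highest or lowest value and its nearest neighbour was divided by the whole range, for named genes (log2 CPM), list scores and library measures. The ratio passed the 95% limit in 21 of 338 groups, and chance passes about 1 in 20, or 16.9 of them, so the number itself is close to chance. PBS 1 was the library set apart in 9 of the 21. No explanation was tested for any of these values.

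In PBS 1, Spry1 was low at 0.748 against 2.37 for its neighbour (ratio 0.892), Pmaip1 was low (0.887) and Ciart was low (0.958). Ptpn6 was high at 7.63 against 6.41 (0.836), Ccr9 was high (0.895) and Cdh1 was high (0.884). Its scores of the early T cell activation list, 6.20 against 6.76 (0.949), and of the homing receptor list, 4.31 against 4.74 (0.915), were the lowest of the PBS group. The share of counts held by its 10 most abundant genes was 9.93% against 12.1% (0.833).

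Among the other PBS libraries, Oas3 was low in PBS 2 (0.944), and the natural IEL score was low in PBS 3, at 7.49 against 7.57. Its ratio of 1 came from rounded scores, in which the rest of the PBS group tied at 7.57. In Ex4 2, Cd1d1 was low at 6.13 against 6.37 (0.885) and still above all PBS libraries. In the same library Il10 was low at 3.10 against 5.18 (0.883), Birc5 was low (0.965) and Ccr9 was high (0.862). In Ex4 4, Cyc1 (0.888) and Srm (0.83) were low. Ebi3 was low (0.979) and the Y-linked gene Eif2s3y high (0.927) in Ex4 3. In Ex4 1, Tnfrsf17 was high (0.874) and Fcer2a low (0.838).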

How the results depend on the processing

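The fits with the number of genes detected or the total counts as a covariate and without PBS 2 and Ex4 3 together were chosen after the data were seen, and all other alternatives were fixed before the data were examined. Flna was called in every setting run. It had a log2 fold change from 1.48 to 1.66 over 24 alternatives. The count of genes changed was 75 with DESeq2 (43 higher, 32 lower), 8 without a filter (5 higher, 3 lower), and 1 (1 higher) with limma-voom, the run of label numbers, the epithelial score, the test against a 1.2-fold change or the genes-detected covariate. Leaving out 1 library gave 1 to 14 genes (1 to 10 higher, 0 to 4 lower), with 14 without PBS 2. The total-counts covariate gave 1 higher and 1 lower, Crtam, the replicate block gave 1, and the other settings gave 2 or 3. DESeq2 gave an adjusted p to 12384 genes and none to 12846. The cause of the larger DESeq2 count was not tested. In simulated counts DESeq2 made 24 false calls among 110 and edgeR 7 among 75. That simulation held the 14691 filtered genes, each drawn independently, whereas the real DESeq2 run took the unfiltered table. Its share of false calls need not hold for the real DESeq2 calls.

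Pairing of libraries by the same replicate number was not seen, though no test of it was made. The correlations of same-numbered deviations were 0.09, -0.03, -0.24 and 0.14, and with the replicate block 1 gene was called, 1 of them higher. Cd1d1 had a log2 fold change of 1.01 with the block (edgeR adjusted p = 0.313). It was 1.00 with limma-voom (adjusted p = 0.0667), 1.01 with the run of label numbers (0.0534), 0.957 with the epithelial score (0.198), 1.00 against a 1.2-fold change (0.173), 1.05 with the genes-detected covariate (0.0675) and 0.996 with the total-counts covariate (0.0667). It lay between 0.913 and 1.11 with 1 library left out, and its adjusted p between 1.19e-05 and 0.313 over the 24 alternatives. The call was lost in 14 of them, those just given and 7 with a library left out, which have fewer libraries by construction, and otherwise the cause was not tested. The second principal component separated the groups with an exact p of 0.0286 under the stricter filter.

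With an estimated correlation or with fry, 0 lists were called higher and 0 lower. Adjusted p with an estimated correlation was 0.369 for the unfolded protein list and 0.845 for the cholesterol, ribosome biogenesis, conventional T cell and epithelial lists. With fry it was 0.179, 0.751, 0.404, 0.682 and 0.751 in that order. With 1 library left out, 0 to 2 lists were higher and 3 to 5 lower. The unfolded protein list stayed at or under 0.000268, cholesterol synthesis 0.021 and ribosome biogenesis 0.000294. The conventional T cell list ran from 0.00019 to 0.0999 (without Ex4 3) and had 0.284 with shared members removed, so that 0 lists were then higher. The epithelial list ran from 2.25e-12 to 0.113 (without PBS 3) and had 0.174 with the epithelial score as a term, which removes its own signal.

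Lists not called with all libraries that turned direction are given by adjusted p, and the cause was not tested. With 1 library left out they ran from 0.407 to 0.97 for the GLP-1 pathway, 0.126 to 0.97 for early activation, 0.285 to 0.97 for proinflammatory cytokines, 0.486 to 0.997 for type 2 cytokines, 0.494 to 0.994 for cytotoxic effectors and 0.0455 to 0.971 for NF-kappaB targets. They ran from 0.455 to 0.934 for interferon-stimulated genes, 0.585 to 0.997 for heat shock, 0.118 to 0.97 for oxidative phosphorylation and 0.176 to 0.887 for cell cycle. They ran from 0.00453 to 0.936 for B cells, 0.145 to 0.88 for macrophages and 0.118 to 0.936 for stromal markers. The epithelial score turned the GLP-1 pathway (0.94), early activation (0.7), type 2 cytokines (0.892), oxidative phosphorylation (0.8) and B cells (0.632). The genes-detected covariate turned the GLP-1 pathway (0.95), early activation (0.745), proinflammatory cytokines (0.95), type 2 cytokines (0.993), NF-kappaB targets (0.9), oxidative phosphorylation (0.527), cell cycle (0.197), B cells (0.993), macrophages (0.835), neutrophils (0.993) and stromal markers (0.441). The total-counts covariate turned cytotoxic effectors (0.739), interferon-stimulated genes (0.775) and heat shock (0.868). Without PBS 2 and Ex4 3, type 2 cytokines, heat shock and cell cycle turned (0.924 each). Removing shared members turned NF-kappaB targets, heat shock and clock genes (0.886 each), ranks turned heat shock (0.923), the block turned type 2 cytokines (0.867) and fry turned early activation (0.995). Lists newly called with their direction kept were the cAMP response (0.0281 without PBS 4), T cell receptor signalling (0.0203 without PBS 2), NF-kappaB targets (0.0455) and mast cells (0.0125) without PBS 1, B cells (0.00453 without Ex4 3, and 0.0316 without PBS 2 and Ex4 3) and chemokines (0.0113 without PBS 2 and Ex4 3).

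The named genes that turned direction had not been called. With 1 library left out log2 fold changes ran from -0.573 to 0.242 for Fcer2a, -0.691 to 0.148 for Blk, -0.072 to 0.187 for Uty, -0.435 to 1.05 for Xist, -0.169 to 0.081 for Kdm5d, -0.51 to 0.289 for Il2, -0.132 to 0.089 for Gzmb and -0.283 to 0.016 for Itgae. With the epithelial score Fcer2a was 0.264, Blk 0.293, Uty -0.099 and Il2 0.24. With the genes-detected covariate Kdm5d was 0.09, Il2 0.038 and Itgae 0.01. Gzmb was -0.001 with DESeq2, -0.006 without a filter and -0.021 with the total-counts covariate, Xist -0.006 with the run of label numbers, Uty -0.044 without PBS 2 and Ex4 3, and Kdm5d 0.033 with the surrogate variable. Of 3131 values of 131 other named genes 3072 kept direction and side of the threshold, 26 newly passed it and 33 turned. Of 525 values of 25 lists the numbers were 453, 7 and 65. Depth limits genes at a few CPM, such as Il17a and Glp1r, most.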

Other observations

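The tests of other splits for the unfolded protein and ribosome biogenesis lists and for the DESeq2 count, and the test of library depth for those lists, were chosen after the result was seen. The total-counts covariate and the genes and gene lists named in this part were chosen after the data were seen as well. For the other tests the outcomes had not been seen when their bounds were set, although the patterns had.

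Il17a, Il22, Iltifb, Rora and Il23r were picked after their values were seen, none passed the edgeR test over all genes, and no list fixed beforehand stands for them as a group. The fixed lists of proinflammatory cytokines and of mast and innate lymphoid cells were not called (camera adjusted p = 0.482, direction down, and 0.368). Il17a had a log2 fold change of 3.03 (SE 0.65, edgeR adjusted p = 0.291), Il22 of 1.32 (SE 0.42, adjusted p = 0.499), Iltifb, a near-identical copy of Il22, of 2.16 (SE 0.55, adjusted p = 0.335) and Rora, a transcription factor gene, of 1.46 (SE 0.36, adjusted p = 0.351). Il23r, a cytokine receptor gene, was at 0.311 ± 0.406 and 1.28 ± 0.301 CPM, a log2 fold change of 2.06. With 1 library left out it ran from 1.61 (without PBS 2) to 3.43 (without PBS 4). That of Il17a ran from 2.28 (without Ex4 3) to 3.31 (without Ex4 2). DESeq2 called Il17a (adjusted p = 0.00158), Iltifb (0.0107) and Rora (0.00724). Reads of Il22 and Iltifb may have been divided between the copies, so the 2 values need not be independent. Whether a change of cell composition accounts for the values of these genes was not tested.

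Cars and Iars, 2 cytosolic tRNA synthetase genes, were among the genes DESeq2 called, with log2 fold changes of -0.70 and -0.57 in edgeR (adjusted p = 0.31 for both). The hypothesis of a lower amino acid response across these enzymes was tested on the other 18. Their median log2 fold change was -0.26, and 17 of 18 were below 0, including Kars (-0.41) and Aars (-0.38). A bootstrap over these genes gave a 95% interval from -0.35 to -0.20. It resampled genes, not mice, and took them as independent, so it does not measure the uncertainty over animals. The preset correlation gave a camera p of 4.96e-09 and the estimated correlation, 0.40 between genes, a p of 0.0641. The values suggest a shared shift, but with genes this correlated the test cannot decide.

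Flna and Cd1d1 were higher with exendin-4, and 3 explanations were weighed. Reads moved between paralogs are argued against for Cd1d1, since Cd1d1 and Cd1d2 together had a log2 ratio of 1.01. Stromal or smooth muscle cells in the sort are argued against by 5 of their abundant genes (Col1a1, Col1a2, Col3a1, Acta2 and Myh11), which together reached 11.1 ± 7.69 CPM in Ex4, while Flna rose by 86.4 CPM. A general rise of SRF and actin cytoskeleton genes by as much as Flna (1.58) is argued against by 18 tested SRF targets without Flna. Their median log2 fold change was 0.09, with limits of -0.17 and 0.24 from a bootstrap that resampled genes, not mice. For a smaller rise the test cannot decide, since 11 were higher and 7 lower (camera p = 0.446 at the preset correlation). Of biological explanations only this rise of SRF targets was tested. A smaller rise of them and other explanations stay open, an effect of the treatment by another route among them.

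The unfolded protein and ribosome biogenesis lists were lower with exendin-4, and no Ex4 library reached the PBS libraries in either score. Background transcripts were checked by the fit with genes detected at matched depth as a covariate (medians -0.26 and -0.15, larger camera adjusted p 0.000359). Library depth was checked with total counts (medians -0.28 and -0.22, 9.91e-07) and epithelial cells with the epithelial score (medians -0.24 and -0.23, 7.92e-05). The medians without a covariate were -0.27 and -0.20, so none of these terms took the shift away. These p-values used the preset correlation, and the estimated correlation was not run with a covariate. The p-values therefore cannot decide whether the remaining shift exceeds what members that vary together would give. Gene length, GC content and expression level are argued against by 10000 matched random lists, where the medians lay at percentiles 0 and 0.08. Both lists moved one way with camera p-values as small in 1 of 35 splits, the real one (real 5.13e-07, nearest of the others 5.39e-05), but they were picked from 30 lists after their scores were seen, so that this share understates chance. Both calls were lost with an estimated correlation (adjusted p = 0.369 and 0.845), and no biological explanation was tested, so that the treatment and other causes stay open.

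Cirbp had a log2 fold change of 0.84, which passed DESeq2 (adjusted p = 0.00386) and edgeR without a filter (0.0418) but not edgeR with it (0.249). A lower body temperature after exendin-4 is a candidate explanation, which predicts a rise of Rbm3, the other cold-induced RNA-binding protein gene. Rbm3 was at 150 ± 21.1 and 212 ± 25.6 CPM, a log2 fold change of 0.50 with a 95% interval from 0.20 to 0.80 (edgeR adjusted p = 0.40). The outcome went with the hypothesis, whose bound was a rise of Rbm3 with an unadjusted p under 0.05 in the edgeR test. That bound was weak, since 545 of 14691 genes were higher at that level. Cirbp had been named for its small p-value in these data, and Rbm3 was then chosen from known biology of cold response. Body temperature was not measured, so the cause stays open.

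Other splits of the 8 libraries into 4 and 4 were compared with the real one, 35 in all with the real one included. As many genes as the 2 called by edgeR came up in 2 splits (highest of the others 2), so chance cannot be excluded for the count. The F statistic of Flna, 112, was matched in 1 split, the real one, and the highest of the others was 55. This argues against chance for Flna. Since 1 of 35 is the smallest share that these splits can give, they cannot exclude it. As many lists as the 5 called came up in 29 splits (highest of the others 17), so chance cannot be excluded for the number of lists. With DESeq2 as many genes as the 75 came up in 4 splits (highest of the others 152), so over all 35 splits chance cannot be excluded for that count either. The split with 152 put PBS 1, PBS 3, PBS 4 and Ex4 4, the 4 libraries with the lowest totals, against the rest, and it was also the other split with 2 genes in edgeR. The split of PBS 1, PBS 2, PBS 4 and Ex4 3 against the rest gave 131 and does not follow the totals, and that of PBS 1, PBS 4, Ex4 1 and Ex4 4 gave 82. In each of these splits PBS 2 and Ex4 3 stood on the same side, whereas the real split parts them. These 2 libraries had the fewest genes at matched depth. Among splits that part them, the real one gave the most genes, 75. PBS 1, PBS 2, PBS 3 and Ex4 2 against the rest came next with 14. That comparison was chosen after the counts were seen. Being together did not suffice, since PBS 1, PBS 2, Ex4 3 and Ex4 4 against the rest gave 0. The splits with 152 and 131 kept most PBS libraries on one side, but this did not suffice either. PBS 1, PBS 2, PBS 3 and Ex4 3 against the rest gave 1 gene, and PBS 1, PBS 2, PBS 3 and Ex4 1 gave 0. Whether the treatment adds to the counts of 152 and 131 cannot be told from these splits. What sets these counts was not tested. With total counts as a covariate Flna had a log2 fold change of 1.57 (edgeR adjusted p = 0.0027), and camera at the preset correlation gave adjusted p = 9.91e-07 for the unfolded protein list and 8.49e-10 for the ribosome biogenesis list. Without that covariate both calls were lost with an estimated correlation (adjusted p = 0.369 and 0.845), which was not run with it.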
